A study of Mus musculus with 12 samples.

How the data were processed

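Gene expression was measured by RNA sequencing in 12 libraries of mouse B cells, 3 WT and 3 T58A libraries from marrow cells grown with IL7 and 3 of each from splenic cells grown with LPS. Per the labels, libraries were demultiplexed with bcl2fastq 1.8.4, aligned to mm10 with TopHat2 2.1.0, counted with HTSeq 0.6.1 and analysed with DESeq2, whose version is not stated. The authors deposited for each population a signal per gene and library, which the values show to be a read count divided by 1 size factor per library. They also deposited a log2 fold change, a p-value and an adjusted p per gene for T58A against WT. Dividing each column by its smallest step gave whole reads within 0.001 for 100% of the values, so the reads assigned to genes were recovered for every library. The plan had foreseen raw counts. Because the tables hold normalised values, the test was the one fixed for that case, limma-trend on log2 of the value plus 1.

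Depth was from 5110746 to 10201113 reads assigned to genes per library, and 3 reads, the limit that a count of 0 allows, correspond to 2.15 to 4.12 normalised reads. Such limits cover counting error only. The series design speaks of littermate mice and the titles of pairs, but the labels do not name the animal of each library, so the spread between replicates may be technical in part. The WT libraries of each population hold both sexes and so come from more than 1 animal, while the T58A libraries, all male, do not show this. Gene symbols were matched to GENCODE M21 on GRCm38 for locations, transcript length and GC content, and 23636 of 24015 symbols matched (98.4%). That release may not be the one the authors used.

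Libraries were grouped by genotype and population from the titles and column headers. In the LPS table the header T58A2 stands over a pair of columns, which give the genotype but not the pair number. They are called the first and the second unnumbered column. Low counts were filtered per population with filterByExpr of edgeR 4.0.16 on the recovered reads (minimum count 10, minimum total 15). Genotype was tested with limma 3.58.1 in R 4.3.3, within each population, without a block for the pair, at a Benjamini-Hochberg adjusted p under 0.05. The difference between the populations was tested as an interaction over all 12 libraries. The 28 gene lists were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation and with fry, which tests whether a list's genes move one way on balance and does not compare the list with other genes. At an estimated correlation camera uses the residual degrees of freedom of the fit, which are few here, so that test had little power. Lists with fewer than 2 tested members were left out, which left 26 in each comparison.

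These comparisons, tests, lists and the rule for named genes were chosen before the data were examined. The rule took Myc, then the 10 genes with the largest increase and the 10 with the largest decrease among those with an adjusted p under 0.05, a mean log2 CPM of at least 1 and no overlap between the groups, leaving out predicted genes, pseudogenes and antigen receptor segments. Where none passed in a direction, the 5 with the smallest p were named. For each list the members with the smallest p in each direction were named, and for the interaction 5 genes per direction. Some genes that this rule takes are not reported here. In IL7 cultures the rule was applied both without and with the block, and the use of the block there was decided after the count without it had been seen. Xbp1 and Igj in LPS cultures, Igj in IL7 WT 2 and Cd74 were chosen after their values had been seen.

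Alternatives were other scalings (size factors of DESeq2 1.42.0, total counts, TMM), other filters, pseudocounts of 0.5 and 5 in place of 1, edgeR, limma-voom and DESeq2, all libraries in 1 fit, the pair as a block, and leaving out each library in turn. TMM, the pseudocounts, edgeR on the recovered reads without a block, the block in limma and limma-voom, sex as a covariate, leaving out IL7 pair 2, exchanging the unnumbered columns and a correction for length and GC content were added after the data had been seen. The alternative that leaves out immunoglobulin chain genes was not run, since no such gene is analysed here. The authors' p-values were compared with DESeq2 on the recovered reads. In the IL7 table the fit with the pair as a block gave 98.6% of p-values within 1% of the authors' values and all 1036 of their calls. For the LPS table, 99.7% were within 1% when the first unnumbered column was paired with WT 1, with all 225 calls, and 1 call was made with the columns exchanged. The tests were also tested on simulated counts, drawn for each gene on its own from a negative binomial fit to the IL7 or the LPS libraries. The fit kept the pair effects and had its genotype effect set to 0, and 200 random genes were then given known folds. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.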

Results

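RNA was sequenced from cultured B cells of wild-type (WT) mice and of littermates that carry T58A, a point mutation in MYC at a residue whose phosphorylation marks the protein for degradation. Bone marrow B cells were grown for 48 h with IL7, the cytokine that drives growth of B cell precursors. Splenic B cells were grown for 48 h with LPS, a bacterial product that drives mature B cells to divide and to become antibody-secreting plasmablasts. Each of the 4 groups had 3 libraries, and the titles number them as pairs of a WT and a T58A sample. The IL7 libraries held from 8486753 to 10201113 reads assigned to genes, and the LPS libraries held from 5110746 to 9332410. The 10 most abundant genes took 2.77% to 2.93% of the reads in the IL7 libraries and 4.17% to 5.44% in the LPS libraries.

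Myc itself, on chromosome 15 from 61985391 to 61990374 (GRCm38), was read first in every library. In IL7 cultures its normalised read count was 3024 ± 937 in WT and 4087 ± 934 in T58A (SD, n = 3). It rose in each pair, from 2010 to 3038, from 3204 to 4397 and from 3858 to 4827. With the pair as a block, the log2 change was 0.46 ± 0.07 (SE) with an adjusted p of 0.00791 from limma. Without the block the adjusted p was 0.378. In LPS cultures Myc was at 858 ± 205 in WT and 1024 ± 366 in T58A (SD, n = 3), and its log2 change of 0.22 ± 0.27 (SE) did not pass (limma adjusted p = 1). Mutant and normal Myc transcripts are counted together, so these counts do not test the genotype.

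**Figure D1:**
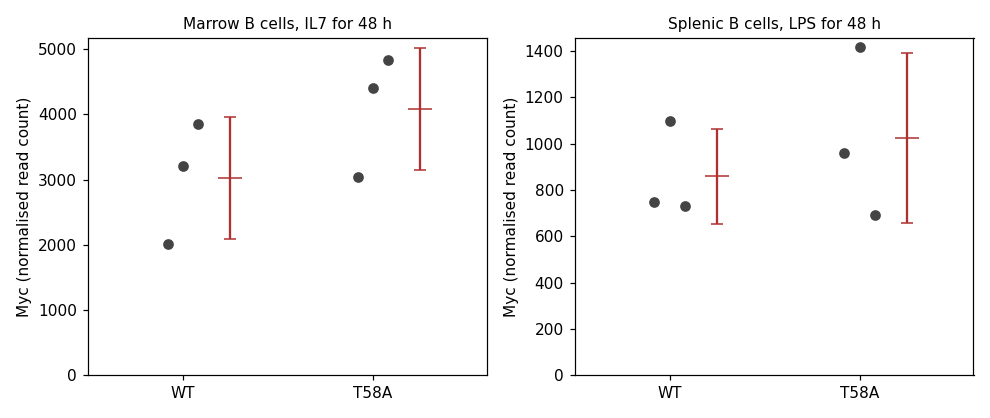
Normalised read count of Myc in each library (points), with the mean and SD of each group in red, for marrow B cells with IL7 and for splenic B cells with LPS. In the IL7 cultures the group means are 3024 and 4087, and in the LPS cultures 858 and 1024.

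The sex-linked transcripts place WT 1 and WT 2 as female and WT 3 and every T58A library as male, in both populations. Sex therefore moved with genotype in pairs 1 and 2, and the pair numbered 3 was the only one of the same sex. Xist, the RNA that silences an X chromosome in females, was at 12436 in IL7 WT 1 and at 23674 in IL7 WT 2. IL7 WT 2 also held Y-linked reads, with 31.7 normalised reads of Kdm5d, 58.9 of Eif2s3y, 42.6 of Ddx3y and 34.4 of Uty. The same library held Igj, the joining chain of secreted antibody, at 611, against 89.1 and 105 in the other WT libraries. Igj averaged 32354 in the male LPS libraries.

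**Figure D2:**
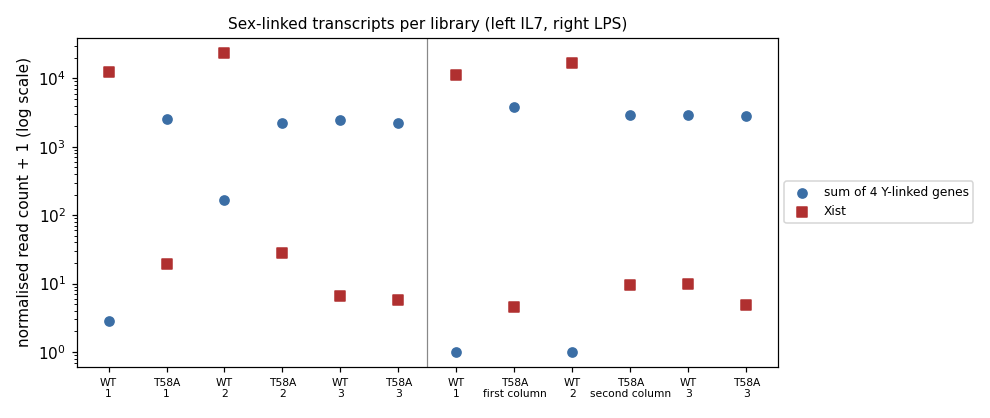
Normalised read counts plus 1 on a log scale for Xist (squares) and for the sum of 4 Y-linked genes (circles) in each of the 12 libraries, with the IL7 libraries on the left and the LPS libraries on the right. WT 1 and WT 2 are high in Xist, the other libraries are high in the Y-linked genes, and IL7 WT 2 shows both.

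The first comparison asks what the T58A mutation changes in marrow B cells grown with IL7. The test fixed in advance, limma without the block, called 0 of 11604 genes, and the block was given weight after that had been seen. With the pair as a block, genes of ribosome production, nucleotide synthesis, lipid synthesis and sugar breakdown rose in T58A cultures. Genes of mature B cells, of NF-kB signalling and of the interferon response fell. Both statements rest on counts of single genes with the block and on camera at its preset correlation. With an estimated correlation camera passed 0 of 26 lists with the pair as a block (smallest adjusted p = 0.417), and fry called 0. That form of camera uses the few residual degrees of freedom of the fit, so it had little power to pass a list. NF-kB targets had an estimated correlation of -0.04, under the preset 0.01, and their camera adjusted p still went from 6.08e-07 to 0.417. For NF-kB targets the lost call therefore does not show that correlation between genes had made it. Other called lists had higher estimated correlations. Among them were ribosome biogenesis at 0.53, cholesterol synthesis at 0.60, myeloid markers at 0.81 and mature B cell genes at 0.09. For lists above the preset, low power and correlation between genes cannot be told apart as the reason for the lost call. With the pair as a block, 744 genes rose and 732 fell among 11604 tested (limma, adjusted p under 0.05). Ranbp17, a nuclear transport receptor, rose 5.64-fold, from 9.08 ± 3.18 to 54.7 ± 13.1 normalised reads (SD, n = 3). H19, an imprinted noncoding RNA, rose 2.45-fold, from 963 ± 157 to 2373 ± 437. Fxyd6, a regulator of the sodium pump, fell from 107 ± 59.3 to 27.9 ± 13.7, a log2 change of -1.86 ± 0.20 (SE).

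Among the 10 genes with the largest increase of those that rose without overlap between the groups were Ranbp17, Bbs7, Mpp3, Kazn, H19, Ephb2, Wnk2 and Ccdc141. Their folds ran from 5.64 in Ranbp17 to 2.41 in Ccdc141. Ranbp17 lies on chromosome 11 from 33211795 to 33513746, and H19 on chromosome 7 from 142575529 to 142578143. Among the 10 with the largest decrease were Cd86, Traf1, Fcrl5, Igj, Fxyd6, Cacna2d1, Gimap3, Pcp4l1 and Phf11b. Their log2 changes ran from -2.45 in Cd86, a costimulatory receptor, to -1.61 in Phf11b. Cd86, Traf1, Fcrl5, Igj and Gimap3 were highest in IL7 WT 2, the library with Y-linked reads, and their log2 changes within pair 2 were -4.67, -3.52, -3.67, -3.82 and -3.12. Cacna2d1 and Pcp4l1 were highest there too, by less, with log2 changes within pair 2 of -2.23 and -2.67. With pair 2 left out, the adjusted p of Bbs7 became 0.123, of Kazn 0.0518, of Cd86 0.0783, of Traf1 0.0857, of Fcrl5 0.0920, of Igj 0.117, of Cacna2d1 0.0531, of Pcp4l1 0.0701 and of Phf11b 0.0769. With sex as a further term, the adjusted p of Fxyd6 was 0.0701, of H19 0.0702, of Mpp3 0.0862 and of Ranbp17 0.0927, and those of the other genes named here were higher.

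Ribosome biogenesis genes rose together in IL7 cultures, 19 of 30 over all genes and 26 of 30 adjusted over the list alone, with a median log2 change of 0.31. Polr1a and Polr1b, subunits of the polymerase that makes ribosomal RNA, changed by 0.64 ± 0.07 and 0.62 ± 0.09 (SE). Of the nucleotide and polyamine synthesis genes, 14 of 27 rose over all genes and 20 adjusted over the list alone, with a median of 0.30. Cad, the enzyme that starts pyrimidine synthesis, went from 3141 to 4990 normalised reads, and Mthfd1 of the folate cycle rose by 0.55 ± 0.06. Of the cholesterol and fatty acid synthesis genes, 12 of 24 rose over all genes and 13 adjusted over the list alone, with a median of 0.30. Fasn, the fatty acid synthase, went from 4359 to 8537. Of the glycolysis genes, 8 of 19 rose over all genes and 9 adjusted over the list alone, with a median of 0.32, among them Ldha (0.57 ± 0.08) and Tpi1 (0.63 ± 0.09).

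DNA replication genes rose in 6 of 32 over all genes and in 11 adjusted over the list alone, with a median of 0.14, among them Pole (0.41 ± 0.07) and Mcm2 (0.33 ± 0.06). Oxidative phosphorylation genes rose in 3 of 30 by both counts, with a median of 0.06, among them Atp5b and Ppargc1b, at 0.33 and 0.73. Camera with its preset correlation called all 6 of these lists up, with adjusted p-values from 1.73e-10 for ribosome biogenesis to 0.0384 for oxidative phosphorylation with the pair as a block. With an estimated correlation, the adjusted p with the block was 0.624 for ribosome biogenesis, nucleotide synthesis, glycolysis and DNA replication, 0.627 for cholesterol synthesis and 0.773 for oxidative phosphorylation. With sex as a further term the T58A effect rests on pair 3 alone, with 1 residual degree of freedom, so the design itself lowers the number of calls. The list medians were then 0.20 for ribosome biogenesis, 0.27 for nucleotide synthesis, 0.51 for cholesterol synthesis, 0.44 for glycolysis, 0.15 for DNA replication and 0.06 for oxidative phosphorylation, and 0, 0, 4, 3, 0 and 0 of their genes rose by limma over all genes. With pair 2 left out, 6, 11, 10, 7, 3 and 1 genes of these lists rose. Without T58A 3 alone the median was 0.13 for glycolysis, 0.16 for cholesterol synthesis and 0.09 for DNA replication. Camera's call was lost for DNA replication without WT 1 (median 0.07), and for oxidative phosphorylation without WT 2 (0.03), without pair 2 in the block (0.04), without T58A 3 (0.05) and with sex as a further term.

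Mature and germinal centre B cell genes fell in IL7 cultures in 20 of 23 over all genes and 21 adjusted over the list alone, with a median log2 change of -0.84. The class II antigen presentation genes H2-Eb1 (2142 to 922 normalised reads) and H2-Ab1 changed by -1.25 ± 0.08 and -1.05 ± 0.06 (SE). NF-kB targets fell in 10 of 17 over all genes and 13 adjusted over the list alone, with a median of -0.67. Cd83, an activation marker, went from 362 to 92.6, and Nfkbia, the NF-kB inhibitor, changed by -0.81 ± 0.10. Interferon response genes fell in 7 of 20 over all genes and 10 adjusted over the list alone, with a median of -0.55, among them Ifi27l2a (372 to 156) and Gbp3 (-0.58 ± 0.07). Early B cell development genes fell in 8 of 26 over all genes and 13 adjusted over the list alone, with a median of -0.17. Rag1, which cleaves DNA in antigen receptor rearrangement, went from 2446 to 1440, and Il2ra changed by -0.64 ± 0.10. Cell cycle inhibitors fell in 6 of 16 over all genes and 8 adjusted over the list alone, with a median of -0.39, among them the antiproliferative genes Btg1 (-0.85 ± 0.09) and Btg2 (-0.81 ± 0.09).

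Immediate early and heat shock genes fell in 4 of 15 over all genes and 7 adjusted over the list alone, with a median of -0.32. Jun changed by -0.84 ± 0.08 and Egr3 by -1.43 ± 0.19 (SE), while the heat shock gene Hsph1 rose by 0.44. Myeloid cell markers had a median of -0.83 with 0 of 11 past limma's test over all genes or over the list alone, although camera called the list at an adjusted p of 0.0388. Their median log2 changes within the pairs were -0.67, 0.44 and -2.93, so they moved with the falling groups in pairs 1 and 3. In pair 2, which holds IL7 WT 2 with its Y-linked reads, NF-kB targets had a median of -0.64 and interferon response genes -0.80. The test of myeloid cells given below covered mature B cell genes only. Whether fewer myeloid cells account for the falls of NF-kB targets and interferon response genes was not tested. Without pair 2, 6 of 12 myeloid markers fell. Camera called these 7 lists down, and with an estimated correlation the adjusted p with the block was 0.417 for mature B cell genes, NF-kB targets and the interferon response. It was 0.538 for early B cell development and immediate early genes, 0.624 for cell cycle inhibitors and 0.812 for myeloid markers. With pair 2 left out, 16 mature B cell genes, 9 NF-kB targets, 5 interferon genes, 8 early B cell genes, 5 inhibitors and 3 immediate early genes fell. With sex as a further term, which rests on pair 3, the medians were -0.75 for mature B cell genes, -0.53 for NF-kB targets, -0.42 for the interferon response, -0.23 for early B cell development, -0.21 for inhibitors, -0.20 for immediate early genes and -2.93 for myeloid markers. By limma 4, 0, 0, 1, 0, 0 and 5 of their genes fell. The immediate early list lost its call by camera without WT 1 (-0.20) and without T58A 2 (-0.22), and with sex as a further term it and early B cell development lost theirs. The myeloid median was -1.41 without WT 2, and the list lost its call without WT 3 (-0.57) and without T58A 3 (-0.48).

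**Figure D3:**
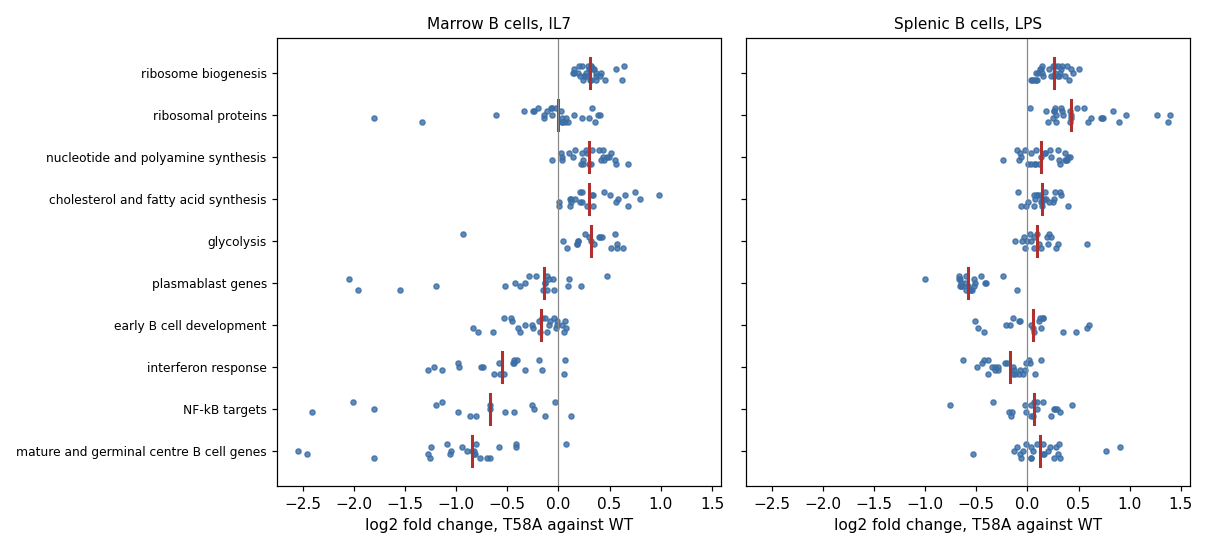
Log2 fold change of T58A against WT (horizontal axis) for every tested member of 10 gene lists, with the list median in red, for IL7 cultures on the left and LPS cultures on the right. Ribosome biogenesis has medians of 0.31 and 0.26, mature B cell genes have -0.84 and 0.12, and plasmablast genes have -0.14 and -0.58.

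The other lists were not called by camera in IL7 cultures, and without the block limma called 0 of their genes over all genes. The counts that follow are those with the pair as a block. In the MYC network list 2 of 14 genes rose and 2 fell, with Mga at 0.31, Mxd1 at -0.51 and Mxd3 at -0.40. In the ribosomal protein list 1 of 28 rose and 3 fell, with a median of 0.00. In the amino acid and stress response list 2 of 18 rose, Slc7a1 at 0.56 and Slc7a5 at 0.39, and Ddit3 fell at -0.53. In the BCL2 family 4 of 13 fell, among them Bmf at -0.77 and Mcl1 at -0.39, and Bok rose at 0.70. Of the p53 targets, 1 of 22 rose (Zmat3 at 0.65) and 3 fell, among them Trp53inp1 at -0.53. Lmo2 fell at -0.67 as 1 of 14 stem and progenitor genes, and 0 of 21 mitosis genes passed limma, where the median was 0.05. Of the plasmablast genes, 1 of 22 rose (Sdc1 at 0.47) and 2 fell, Igj at -2.05 and Sec11c at -0.33. Among markers of other cells, Thy1 (0.56) rose and Il2rb (-1.28) fell of 4 T and NK genes, Car2 (0.50) rose and Itga2b (-1.05) fell of 3 erythroid and megakaryocyte genes, and 0 of 4 dendritic and 0 of 2 stromal genes passed limma over all genes. Adjusted over the list alone 2 dendritic and 1 stromal genes fell, with medians of -0.40 and -0.67, as did 6 p53 targets, while 4 stress response genes and 2 p53 targets rose. In the other lists of this kind the count adjusted over the list alone equalled that over all genes, apart from the sex-linked genes. Of 5 sex-linked genes, 1 fell over all genes and 4 rose and 1 fell adjusted over the list alone. With pair 2 left out, 1 MYC network, 3 ribosomal protein, 2 stress response, 1 BCL2 family, 1 plasmablast and 1 erythroid gene rose over all genes, and 3 ribosomal protein, 3 BCL2 family and 2 p53 genes fell. None of the stem, mitosis, T and NK, dendritic, stromal and sex-linked genes then passed. With sex as a further term, 2 ribosomal protein genes fell and 0 genes of the other lists named here passed limma. No immunoglobulin constant region or mast cell gene was among those tested.

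The test fixed in advance, limma without the block, called 0 of 11604 genes in IL7 cultures. At an unadjusted p under 0.05 it held 1960 genes, where 580.2 were expected by chance, and the smallest adjusted p was 0.133. Without the block DESeq2 called 302 and edgeR and limma-voom called 0. Among the 5 genes with the smallest p in each direction were H19, Ranbp17, Nup214 and Slamf7 of the higher, and H2-K1, H2-Q4, Gimap6, Il10ra and Slfn2 of the lower, all at an adjusted p of 0.133. The pair numbers matched the values, since the deviations from the group mean correlated by 0.41, 0.15 and 0.40 across genes between samples of the same number and by -0.36 to -0.05 between samples of different numbers. The block was given weight after the count without it had been seen. In 1492 genes all 3 T58A libraries lay above all 3 WT libraries and in 1253 below, 23.7% of those tested against 10% by chance. The authors' deposited table holds 502 higher and 534 lower genes at an adjusted p under 0.05. With sex as a further term in the block, a fit that rests on pair 3 with 1 residual degree of freedom, 42 genes passed. With pair 2 left out 775 passed.

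The comparison in LPS cultures asks the same of mature B cells driven to divide and differentiate. All 29 tested ribosomal protein genes and all 30 ribosome biogenesis genes had a higher mean in T58A, and all 23 plasmablast genes had a lower one, but no single gene passed the test fixed in advance. Rpl37a, a ribosomal protein gene on chromosome 1 from 72711290 to 72713813, was at 144 ± 29.4 in WT and 632 ± 200 in T58A (SD, n = 3), a log2 change of 2.09 ± 0.27 (SE) with a limma adjusted p of 0.259. Dhrs1, a dehydrogenase, was at 1393 ± 230 and 735 ± 168 (SD, n = 3), a log2 change of -0.93 ± 0.20 (SE) with a limma adjusted p of 1. With a pair block that puts the first unnumbered T58A column with WT 1, both passed, at limma adjusted p-values of 0.00321 for Rpl37a and 0.0494 for Dhrs1. Rpl37a is not a member of the ribosomal protein list, and reads lost to near-identical pseudogene copies were not examined for it. Next by p without the block were Msrb3 (1.32), Smyd2 (0.89), Pvrl1 (1.09) and Mgmt (1.41) among the higher genes, and Hist1h2bc (-1.76), A4galt (-0.96), Il5ra (-0.72) and Epcam (-0.85) among the lower. None of these passed with or without that block.

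The ribosomal protein list had a median log2 change of 0.42, with Rps19 at 797 normalised reads in WT and 1512 in T58A and Rpl12 at 0.84 ± 0.23 (SE). Ribosome biogenesis had a median of 0.26, with Nop56 at 0.43 ± 0.15 and Dkc1 at 0.50 ± 0.18. The plasmablast list, genes of antibody secretion, had a median of -0.58. Its regulator Prdm1 was at 2533 in WT and 1698 in T58A, a log2 change of -0.60 ± 0.21, and Derl3 of protein disposal in the endoplasmic reticulum was at -0.65 ± 0.24. Xbp1 was at -0.64 ± 0.42, and Igj averaged 46688 in WT and 23327 in T58A. In each of these 3 lists 0 members passed limma over all genes and 0 adjusted over the list alone. With a pair block that puts the first unnumbered T58A column with WT 1, 21 ribosomal protein, 9 ribosome biogenesis and 19 plasmablast genes passed adjusted over the list alone, and 1, 0 and 0 over all genes. With the columns exchanged, a pairing that the authors' p-values go against, 0 passed by either count. In pair 3, the pair of males, whose partner the headers give, the medians were 0.27, 0.03 and -0.27. In pairs 1 and 2, with the first unnumbered column put with WT 1, they were 0.47 and 0.33 for ribosomal proteins. They were 0.45 and 0.21 for ribosome biogenesis and -0.96 and -0.52 for plasmablast genes. The rise of ribosome biogenesis was thus nearly absent in the only pair of the same sex, at percentile 79.2 of random lists matched on level. Without WT 2 the ribosome biogenesis median was 0.13, and without WT 1, the first unnumbered column or T58A 3 it was 0.16. Without the first unnumbered column the ribosomal protein median was 0.26. The authors' deposited table calls 11 ribosomal protein genes and 3 ribosome biogenesis genes higher and 13 plasmablast genes lower at an adjusted p under 0.05. In that table Prdm1 has a log2 change of -0.52 (adjusted p = 0.000289), Xbp1 -0.57 (1.20e-05), Igj -0.86 (9.35e-11) and Rps19 0.81 (6.53e-09).

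Camera with its preset correlation called 8 of 26 lists in LPS cultures, 5 higher and 3 lower. Besides the 3 above these were nucleotide and polyamine synthesis (median 0.14, adjusted p = 0.00689), cholesterol and fatty acid synthesis (0.14, 0.0272), the amino acid and stress response (-0.19, 0.0322), the interferon response (-0.17, 0.0139) and the sex-linked genes. With an estimated correlation the adjusted p was 0.626 for ribosomal proteins, ribosome biogenesis, nucleotide synthesis, plasmablast and sex-linked genes, and 0.822 for the other 3 lists. Single libraries turned the weaker medians. Without WT 1 the stress response median was 0.06 and the cholesterol median 0.02. Without T58A 3 the cholesterol median was -0.01 and the nucleotide synthesis median 0.07. Without WT 2 the nucleotide synthesis median was 0.06, as it was without the first unnumbered column. Without the second unnumbered T58A column the interferon median was 0.09, and without WT 2 it was -0.07. Without WT 3 the stress response median was -0.59 and the cholesterol median 0.29, and without T58A 3 the interferon median was -0.42. The number of lists called was 5 without the first unnumbered column or T58A 3. Medians of the remaining lists, none of them called, were 0.13 for the MYC network, 0.09 for glycolysis, 0.03 for oxidative phosphorylation, 0.05 for DNA replication, -0.08 for mitosis, 0.08 for cell cycle inhibitors, 0.03 for the BCL2 family and 0.10 for p53 targets. They were 0.17 for stem and progenitor genes, 0.06 for early B cell development, 0.12 for mature B cell genes, 0.06 for NF-kB targets and -0.01 for immediate early genes. Markers of other cells had medians of 0.22 (myeloid), 0.53 (erythroid), 0.08 (dendritic), -0.66 (stromal) and 0.00 (T and NK), none of them called.

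Limma called 0 of 11291 genes in LPS cultures, with 284 at an unadjusted p under 0.05 where 565 were expected by chance. DESeq2 called 4, and edgeR and limma-voom called 0. In 350 genes all T58A libraries lay above all WT libraries and in 373 below, 6.40% against 10% by chance. The authors' deposited table holds 80 higher and 145 lower genes at an adjusted p under 0.05. A pair block needs the partner of each T58A library, and the same header stands over the T58A columns of pairs 1 and 2. With the first such column paired to WT 1, limma called 4 genes and DESeq2 228, and with the columns exchanged they called 0 and 3. DESeq2 in the first pairing gave 99.7% of the authors' p-values within 1%, against 17.0% in the exchanged one.

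The last comparison asks whether the T58A effect differed between the populations. Limma's test of the difference called 0 of 12184 genes, with 551 at an unadjusted p under 0.05 where 609 were expected, DESeq2 called 3, and edgeR and limma-voom called 0. Mpeg1, a pore-forming gene of phagocytes, had the smallest p, with log2 changes of -1.14 in IL7 and 0.27 in LPS cultures and a difference of -1.41 ± 0.27 (SE, adjusted p = 0.995, limma). The next lower were Wfdc17 (-2.16), Gimap3 (-1.87), Pik3ip1 (-1.23) and Rdh12 (-1.01), and the higher were Slamf7 (0.74), Myl10 (1.59), Spire1 (1.16), Mogs (0.55) and Pdzd2 (1.18), none of which passed without the block. Camera with its preset correlation called 13 of 26 lists, among them mature B cell genes, with a median difference of -1.04, and ribosomal proteins, with -0.42. With an estimated correlation it called 0, and the smallest adjusted p was 0.179. The pair block called 373 genes with the first unnumbered T58A column paired to WT 1, the pairing that the authors' p-values show, and 0 with the columns exchanged. In the first of these fits the genes named here passed, with limma adjusted p from 0.00364 (Pik3ip1) to 0.0494 (Gimap3), apart from Spire1 (0.0550).

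Of the genes with an adjusted p in both of the authors' deposited tables, 5302 in all, 9 were higher in both where 5.35 were expected (Fisher's exact test, two-sided, p = 0.110), and 19 were lower in both where 11.98 were expected (p = 0.0444). A further 3 were higher in IL7 and lower in LPS cultures (9.54 expected, exact p = 0.0251) and 10 the reverse (6.72 expected, exact p = 0.217). Across the 10767 genes tested in both populations, the log2 changes correlated with a Pearson r of 0.284 and a Spearman rho of 0.227, and 58.3% had the same sign. Genes are not independent replicates.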

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

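The tests of the Y-linked reads, of pseudogene copies, of sex, of a library left out and of myeloid cells were chosen only after the results were seen, and the test on length, GC content and level and the splits of the samples were written before. The splits of the list counts within pairs were added later, before their counts were seen. The criteria of the tests of sex and of myeloid cells were made stricter after their first values had been seen, which moved sex from excluded to open.

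The T58A effect differed between IL7 and LPS cultures for 13 gene lists by camera at its preset correlation in the test of the difference itself. With an estimated correlation 0 of the 26 lists passed, and the smallest adjusted p was 0.179 for cell cycle inhibitors and NF-kB targets. The median difference of log2 changes, IL7 minus LPS, was -1.27 for myeloid markers, -1.04 for mature B cell genes, -0.97 for NF-kB targets, -0.42 for ribosomal proteins, -0.35 for cell cycle inhibitors, -0.28 for the interferon response and -0.27 for early B cell development. It was 0.37 for plasmablast genes, 0.28 for the amino acid and stress response, 0.24 for cholesterol synthesis, 0.18 for glycolysis, 0.17 for nucleotide synthesis and 0.14 for mitosis. Of 100 drawn splits of the libraries 4 gave as many lists, the real one included, with 14 as the highest of the others, but these splits ignore the pairs. Of the 32 splits that exchange libraries within pairs 4 gave at least 13, with 14 as the highest of the others, so chance is not excluded for the 13 lists. These splits include the one that exchanges every LPS pair and no IL7 pair, which measures the sum of the T58A effects and not chance. With the pair as a block the real count was 15 and the highest other 13, with 1 of 32 as large. That share is under 0.05, given the pairing of the unnumbered columns that the values show, but 1 of 32 is the smallest share these splits can give. The block was added after the data had been seen, and without it 4 of 32 splits gave at least the real count. Chance is therefore not taken as excluded for the 15 lists either.

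IL7 WT 2, a library high in Xist, held Y-linked reads at 7.03% of the level of male IL7 libraries, against 0.0778% in IL7 WT 1, which argues against differentiated B cells of the same female animal as their source. A set of 24 genes averaged at least 500 normalised reads in male LPS libraries with an IL7 median under 2% of that, and 95.8% of them were highest in IL7 WT 2, which argues against a male IL7 culture. The share of a male LPS library that the Y-linked reads would need is 5.43%, and that for the 24 genes is 4.27%, a ratio of 1.27. A candidate explanation is that reads or RNA of a male LPS library are in IL7 WT 2, and across the 24 genes its log2 values correlated best, at 0.961, with the second unnumbered T58A column. Whether this arose at the bench or in sequencing was not tested, and no biological explanation beyond the same animal's cells was tested.

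Ribosomal protein genes had higher means in T58A LPS cultures, but 0 of 29 passed limma without the block, and camera's call was lost with an estimated correlation (adjusted p = 0.626). Their median log2 change of 0.42 lay at percentile 100 among 10000 random lists matched on length, GC content and level. This argues against those gene properties as the whole cause. The 15 better counted members had a median of 0.28 and the others 0.72. Pair medians of these 15 were 0.39, 0.23 and 0.20 in the pairing that the values show. The lowest pair median was 0.062 with the unnumbered columns exchanged. The headers do not give the pairing, but the exchanged one gave 17.0% of the authors' p-values within 1%, against 99.7% (DESeq2). Being better counted does not show that a gene is free of near-identical pseudogene copies. Reads lost to such copies therefore cannot be told apart from a change in the genes, in these 15 or in the other members. In the single pair of males the median was 0.27, at percentile 100 of random lists matched on level, so the rise was not absent there. Sex still cannot be told apart, because 1 pair gives no spread of its own. The list differs by up to 0.73 between T58A males, but these are of different pairs. That difference holds the pair effect, which a change within a pair removes, so it does not measure the spread of such a change. The genotype itself stays open as an untested biological explanation.

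Mature B cell genes had lower means in T58A IL7 cultures, with 20 of 23 past limma with the pair as a block and 0 without it, and camera's call was lost with an estimated correlation (adjusted p = 0.417 with the block and 0.584 without). The pair medians were -1.04, -0.97 (-0.48 with the larger estimated LPS share taken off IL7 WT 2) and -0.75, and without pair 2 the list median was -0.92, which argues against the reads in IL7 WT 2 as the whole cause. Fewer myeloid cells as the whole cause is argued against for 15 members left after 8 that myeloid cells also express were set aside: with that share taken off, their median fell in every pair, least in pair 2, at -0.43, where myeloid markers had a median of 0.44. A narrower set of 6 members, tried first, gave -0.17, -0.44 and -0.53. For the 8 shared members, class II genes and Cd74 among them, a change in other antigen-presenting cells stays open. The pair of males, at -0.75, lay at percentile 0 of random lists matched on level, so the fall was not absent there. Sex still cannot be told apart from genotype, since this is the only pair of the same sex and gives no spread of its own. T58A males differ from each other by up to 1.21, but they are of different pairs. That difference holds the pair effect and does not measure the spread of a change within a pair.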

How the results depend on the processing

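The block in limma and limma-voom, sex as a covariate, leaving out pair 2, the exchanged columns, TMM, the pseudocounts, edgeR without a block and the correction for length and GC content were chosen after the data had been seen, and the other alternatives were planned. Of the results that answer a comparison, 93 alternatives gave a count within 1.5 times of the one reported and 57 did not.

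In IL7 cultures the count of 0 by limma was 302 in DESeq2 without the block, 1424 in edgeR, 1049 in DESeq2, 1476 in limma and 1468 in limma-voom with the replicate block, and 0 to 2 with 1 library left out (2 without WT 3, 1 without WT 1 or T58A 2). The count of 1476 with the replicate block was 0 without it, 42 with sex as a covariate (where pair 3 alone carries the effect), 775 without pair 2 and 840 without pair 3. Total counts alone moved the split from 744 higher and 732 lower to 576 and 867, and the correction for length and GC content gave 1977 genes.

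In LPS cultures the count of 0 by limma was 4 in DESeq2, 1 with sex as a covariate, and with the replicate block 39 in edgeR, 228 in DESeq2, 4 in limma and 67 in limma-voom. With the unnumbered columns exchanged DESeq2 gave 3, and limma, limma-voom and edgeR gave 0. With 1 library left out it was 0 to 6, with 6 without WT 3 and 1 without T58A 3. The 4 genes of the replicate block were 0 without the block, without a filter or with columns exchanged, 1 with a mean of at least 10 reads or the length and GC correction, 10 with sex as a covariate, 41 with TMM, 39 in edgeR, 67 in limma-voom, 228 in DESeq2, 25 without pair 1, 54 without pair 2 and 352 without pair 3. The pairing of the unnumbered columns is read from the values, where the named pairing gave correlations of 0.34 and 0.66 and the exchanged one -0.23 and -0.22. The test of the difference between populations, with 0 genes, gave 3 in DESeq2, and with the replicate block 373 in limma, 433 in edgeR, 483 in DESeq2 and 417 in limma-voom, 1 with sex as a covariate, 169 without IL7 pair 2 and 0 with columns exchanged. With 1 library left out it was 0 to 3, with 3 without IL7 WT 3 and 1 without IL7 T58A 2.

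The 13 lists called in IL7 cultures were 0 with an estimated correlation and 1 by fry, and 0 and 0 with the replicate block. Camera at an estimated correlation had little power here, because it uses the few residual degrees of freedom of the fit. The 8 in LPS cultures were 0 by each of these, and 5 to 10 with 1 library left out (10 without WT 1, 5 without the first unnumbered column or T58A 3). With the replicate block and sex as a covariate, a fit that rests on pair 3 with 1 residual degree of freedom, the LPS medians were 0.27 for ribosomal proteins, 0.03 for ribosome biogenesis (call lost), 0.05 for nucleotide synthesis (call lost), 0.13 for cholesterol synthesis (call lost), -0.27 for plasmablast genes, 0.32 for the interferon response (called, turned) and 0.15 for the stress response (call lost). Of the 8 calls, 2 kept their direction and their call. The 13 for the difference were 0 with an estimated correlation and 0 by fry, and 0 and 4 with the replicate block. The cause of these moves was not tested. In simulated data limma without the block found 61.8% of 2-fold changes in IL7 and 10.6% in LPS cultures with 0 false calls, and with the block 85.5% and 78.8% with 7 and 12 false calls. The simulated counts held the pair effects by construction, so a gain from the block was built in. They had independent genes and no sex difference between the genotypes, so the false calls do not measure error in the real data.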

Other observations

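The splits of the samples were planned, and the readings of the single genes in this part were chosen after their values had been seen.

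Cd74, the chaperone of class II antigen presentation, fell in every IL7 pair, from 22038 to 9212, from 9732 to 4946 and from 5563 to 2738 normalised reads. Its log2 change was -1.09 ± 0.07 (SE) with the replicate block. Slfn2, a gene of lymphocyte quiescence, changed by -1.21 ± 0.09 and H2-K1 of class I antigen presentation by -0.64 ± 0.06. Nup214, a nuclear pore gene, rose by 0.46 ± 0.06. Myl10 in LPS cultures was at a log2 change of -1.88, against -0.29 in IL7 cultures.

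With 3 libraries against 3, 10 splits exist, too few for a share under 0.05. For a real count of 0 genes a split cannot give fewer, so the splits of the gene counts without the block test nothing about chance. In IL7 cultures the real split gave 0 genes and the highest other 1. The lists were 13 against 13, where 2 splits gave as many and the other one exchanges WT 3 and T58A 3. The median over the other splits was 8 lists. With the replicate block 4 splits exist, also too few, with 1476 genes in the real one, 0 in the highest other and 1 split as large. In LPS cultures the real split gave 0 genes and the highest other 307, and 8 lists against 12, with 6 as large. The split with 307 sets WT 1, WT 3 and T58A 3 against the other libraries, which points to a structure of the LPS samples other than genotype. With the replicate block it was 4 genes against 0, with 1 of 4 splits as large. For the difference between the populations the real count was 0 genes and the highest of 100 drawn splits 304. With the replicate block 2 of 32 splits gave at least 373, with 1339 as the highest, so chance is not excluded for that count. The splits include the one that exchanges WT and T58A in every LPS pair and in no IL7 pair. It measures the sum of the T58A effects and not chance. Whether it is the split that gave 1339 was not examined.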
